A study of Mus musculus with 37 samples.

How the data were processed

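Single cells were measured by Drop-seq, a droplet method that captures the polyadenylated RNA of each cell on a barcoded bead. The cells were mouse embryonic fibroblasts (ICR background) collected 7 days after infection with retroviral vectors that carry a pool of 48 factors, per the labels. The labels give 37 samples, technical replicates 1 to 37 of 1 biological replicate, all with the same pool and without untreated cells. The comparisons are therefore between cells of the same culture that differ in the factor transcripts detected in them, and every p-value measures only the technical spread between libraries of 1 culture.

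The deposited values are raw counts per gene and cell barcode, with no normalization. Per the labels' processing notes, the authors used bcl2fastq 2.17.1.14, STAR 2.5.3a, UMI-tools (version not stated) and featureCounts 1.5.3 on build mm10. The annotation release, the strand setting, the filter on cells and the treatment of reads that map to several places are not stated there. Each table held 27999 gene rows. Of these, 27998 were Ensembl identifiers, 27645 of which matched a symbol in the reference table and 353 did not. The remaining row, for the reporter EGFP, held 0 counts in all libraries. Of the 48 factors, 43 had a row, and the 5 microRNAs of the pool are not analysed here. Positions are from GENCODE M21 (GRCm38), which may not be the annotation the authors counted on. Strand was not stated, so values of genes that overlap another gene are uncertain: this holds for 37 of the 228 named genes. Among genes with at least 20 counts, 19 had counts identical to those of another gene, 4 genes of the Ugt1a locus with 1283 counts each among them.

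Technical replicates 4 and 6 shared 59 cell barcodes, while no other pair of libraries shared more than 4, so these replicates were treated as 1 library and 36 libraries entered the comparisons. Of barcodes found in more than 1 library, or 1 base apart in the same library, only the copy with the most counts was kept. This removed 167 of 8730 barcodes, 89 shared ones and 78 near ones, and left 8563 cells. The minimum of 500 counts per cell removed none, since the lowest total was 1541. No doublet caller was run, and a setting without the 5% of cells with the most counts in each library was used in its place. This setting need not remove doublets of cells with ordinary totals. By the library names in the labels, the libraries came in 3 series, called JD (15 libraries, 3294 cells), PZ47-PZ48 (15 libraries, 3767 cells) and PZ58 (6 libraries, 1502 cells).

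A cell was called with a factor when it held at least 1 count of the factor's gene. Such a count cannot tell a delivered from an endogenous transcript, and cells that carry a factor without a detected count stay among the cells without it. For each factor, the cells with it were matched 1 to 1 with cells of the same library without it on total counts, in libraries with at least 3 cells with the factor, and both sets were summed per library. Genes with at least 20 counts over these sums were tested with the quasi-likelihood test of edgeR 4.0.16 with TMM scaling and the library as a block, at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are from the same fit. The factor itself was left out. The factors were the 8 with the most cells among 13 fixed beforehand (Mef2c, Gata6, Hand2, Mesp1, Foxn4, Tbx5, Nkx2-5 and Isl1). Myod1, Myocd and Gata4 were added after their numbers of cells had been seen. On simulated counts in which 100 genes were changed 2-fold and 100 genes 4-fold, the same test found between 79 and 98 of the former and between 99 and 100 of the latter, depending on the factor. False calls were between 0 and 12. The changed genes were drawn from those with at least 100 counts. All genes had the same dispersion, and libraries differed in size alone. Recovery of genes with fewer or more variable counts was therefore not measured.

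The genes named were chosen by a rule fixed before the data were examined, as were the tests, the gene lists and the cell type markers. Some genes the rule chose are not reported. For Mef2c, Gata6 and Hand2 the rule takes the 10 highest and 10 lowest log2 fold changes past the threshold with the same sign in each of the 3 series, and up to 4 members per list past the threshold with the smallest adjusted p. For the other factors it takes the 3 highest, the 2 lowest and up to 2 members per list.

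The 20 fixed lists hold markers of cardiomyocytes, skeletal muscle, smooth muscle, epicardium and mesothelium, endothelium, macrophages, fibroblasts, nerve and glia, chondrocytes, keratinocytes and other epithelia, and adipocytes, and genes of S phase, of G2 and M phase, of the interferon response, of the p53 response, of the immediate early response, of Notch, BMP or TGF-beta and retinoic acid signalling, and of the mitochondrial genome. Factors of the pool were left out of every list. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists and factors, with camera at an estimated correlation and fry beside it. For 41 factors with at least 6 libraries of at least 3 cells and at least 60 cells in all, the summed CPM (counts of a gene per 1e6 counts) of each list were also compared between cells with and without the factor by a 2-sided permutation test over libraries (signs flipped in 100000 draws, exact under 10 libraries). Log2 ratios of lists are of CPM pooled over libraries.

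Co-detection of factor pairs was compared with independence within library and 3 strata of total counts. Cells with 0, 1 and more than 1 of Gata4, Mef2c and Tbx5 were compared in depth-matched sets. Cells were clustered by Leiden (leidenalg 0.10.2, python-igraph 0.11.9) at resolution 0.5 on a shared nearest neighbour graph (20 neighbours, 30 principal components of 2000 variable genes) without the pool factors. The share of cells with each factor was compared between a cluster and depth-matched other cells of the same libraries. A cluster was named from the fixed markers where at least 3 of them were at least 4-fold higher in it and present in at least 10% of its cells, with at least 1 of them among its 10 leading genes; these numbers were set after the clusters had been seen.

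Some choices were made only after the data had been seen. Libraries were put into a high and a low read class by the ribosomal gene Rps27a, above or below 100 CPM (10 and 26 libraries). Cells were also clustered after centring each gene within read class. The comparisons were repeated without the skeletal muscle-like, mesothelial-like, glial-like and macrophage-like cells, which selects cells by their expression, within each read class, with limma-voom, with all barcode copies kept, and in cells thinned to 1500 counts. The alternatives fixed beforehand were DESeq2 1.42.0, no scaling factor, other filters on counts (none and at least 100), all cells of the library in place of matched ones, at least 2 counts of the factor, no library block, each series alone, the setting without the deepest 5% of cells, cells thinned to 500 counts, and Leiden resolutions of 0.3 and 1. Other splits of the cells were made by swapping the sums with and without the factor at random within libraries.

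Total counts of the kept cells per library were 3237741 ± 1355911 (SD, n = 37 libraries, with technical replicates 4 and 6 counted apart). They ranged from 637680 to 6195462. Intervals of shares are exact Clopper-Pearson intervals at 95%. Where a share is 0, the upper limit that a count of 0 allows is 3 cells of the total; it limits cells with a count, not cells that express the gene. Both cover counting error only. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3. Near-identical gene copies were searched with blastn 2.17.0.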

Results

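Gene expression was measured by Drop-seq in single mouse embryonic fibroblasts that had received a pool of 48 factors by retroviral infection 7 days earlier. The 37 deposited libraries are technical replicates of 1 biological replicate and form 1 group without a control. They held 121818134 counts from 8730 barcodes, of which 8563 cells with 119796414 counts were kept in 36 libraries. After removal of barcode copies, a library kept 231 ± 102 cells (SD, n = 37, with technical replicates 4 and 6 counted apart). These cells held 3237741 ± 1355911 counts per library, from 637680 to 6195462. The median cell of a library had 9210 ± 3190 counts, from 3563 to 15695, and over all cells the median was 8558 counts from 3568 genes. Transcripts of the mitochondrial genome made up 0.537 ± 0.0740% of the counts. Median counts per cell were 8908 in the JD series, 7971 in PZ47-PZ48 and 9335.5 in PZ58. P-values throughout measure the spread between libraries of the same culture and do not extend to other cultures.

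Libraries fell into 2 classes by part of the genes of the ribosome. Rps27a, which encodes a ubiquitin fusion protein of the small subunit, stood at 1012 ± 186 CPM in 10 libraries (the high read class) and at 9.09 ± 2.82 CPM in 26 (the low read class). Rpl3 of the large subunit behaved likewise, at 1044 ± 315 against 7.36 ± 3.30 CPM, and so did the glycolytic gene Gapdh, at 187 ± 115 against 6.79 ± 2.46 CPM. The ribosomal gene Rps14 did not split and was slightly lower in the high class, at 1783 ± 332 and 2246 ± 325 CPM, and the cytoskeletal gene Actb did not split either, at 6764 ± 1036 and 6565 ± 763 CPM. All 6 libraries of PZ58 and 4 of JD were in the high class, and all 15 of PZ47-PZ48 and 11 of JD in the low one. The 4 of JD were technical replicates 1, 2, 3 and 16, which are named with a pair of numbers. The names of the 11 others end in a letter. Of the genes that differed at least 4-fold between the classes, all 61 were higher in the high class, and 34 of them were ribosomal, out of 81 ribosomal protein genes at 20 CPM or more. For this reason, values within series and within class are given for the leading lists of Mef2c, Gata6, Hand2 and Nkx2-5.

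The first question was which factors of the pool could be seen in the cells. Cdkn1a, an inhibitor of the cell cycle, was detected in 90.5% of cells, and the cofactor Lbh, the histone deacetylase Hdac2 and the muscle regulator Mef2a in 72.6%, 72.1% and 65.5%. The cardiac and mesodermal regulators were rarer. Mef2c was detected in 26.0% of cells (95% interval 25.1 to 27.0; 26.2 ± 5.31%, SD over 36 libraries), Gata6 in 23.4% (23.0 ± 3.92%) and Hand2 in 10.6% (4.29% to 16.6% over libraries). Mesp1 reached 5.87%, Foxn4 5.29%, Tbx5 5.22%, Nkx2-5 4.67%, Isl1 4.64%, Myod1 4.11%, Myocd 3.06% and Gata4 2.49%, while Hand1 (94 of 8563 cells), Gata5 (0.596%) and Msc (0.245%) were lowest. The share with Mef2c was 25.9% in JD, 25.5% in PZ47-PZ48 and 27.8% in PZ58. A cell held a median of 9 of the 43 measured factors, and 45.9% of cells held none of the 8 modelled ones. Such counts may be of endogenous transcripts, so they do not give the number of delivered factors in a cell. Cells with a factor were deeper, for Mef2c with a median of 13127 counts against 7585 in all cells without it, so cells were matched on depth before comparison. The matched medians were 13127 and 13131.5, but the means 21167 and 18146. Free RNA was judged from the 28 macrophage-like cells of the clustering centred within read class, with a median of 6742 counts against 8583 in the other cells. None of the 28 held Foxn4, Mesp1, Gata4, Myod1, Nkx2-5 or Myocd, and a count of 0 allows a share of up to 10.7%, which is above the shares of these factors in the other cells. Gata6 and Tbx5 were each found in 3 of them (10.7%, interval 2.27 to 28.2, against 23.4% and 5.20% of the other cells), and Hand2 and Isl1 in 1 each (3.57%, interval 0.0904 to 18.3, against 10.7% and 4.64%). These few cells therefore exclude free RNA for none of these factors, and the share of Tbx5 in them was not below that in the other cells. Mef2c was found in 22 (78.6%, interval 59.0 to 91.7), and as macrophages are known to transcribe Mef2c they give no background for it.

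**Figure D1:**
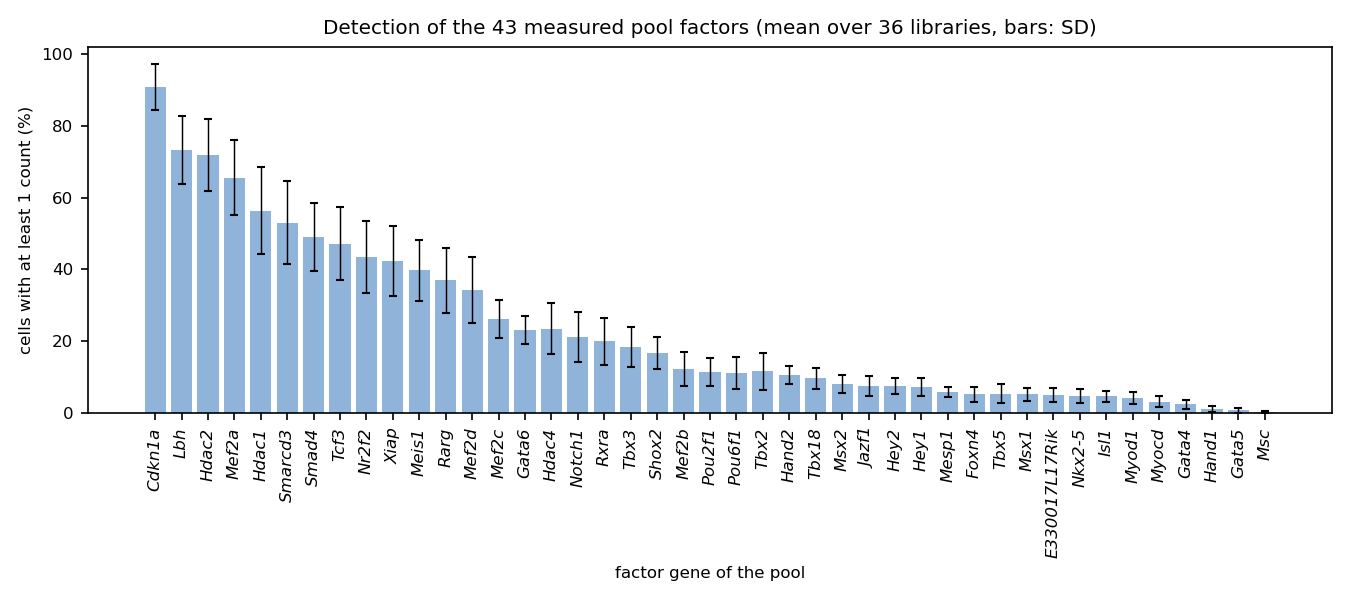
Percent of cells with at least 1 count of each of the 43 measured factor genes, as the mean over 36 libraries with SD. Shares run from 90.5% for Cdkn1a to 0.245% for Msc over all cells, and Mef2c, Gata6 and Hand2 stand at 26.0%, 23.4% and 10.6%.

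Cells with Mef2c, a factor of cardiac and skeletal muscle development, were set against cells without it to see which genes went with it. Genes of skeletal muscle led. Embryonic myosin Myh3, the sarcomere gene Actn2, the fast myosin light chain Mylpf and the myogenic regulator Myog were all far higher in cells with Mef2c, and so were Tnni1 and Ttn. Genes of macrophages (Ctss, Lyz2) and the glial regulator Sox10 were higher as well, while the smooth muscle genes Cald1 and Tagln, the fibroblast regulator Prrx1 and the surface protein Thy1 were lower. Myh3 (ENSMUSG00000020908, GRCm38 chromosome 11, 67078300 to 67102291) stood at 96.2 ± 89.9 CPM in 2230 cells with Mef2c and at 1.42 ± 1.75 CPM in as many matched cells without it (SD, n = 36 libraries). Its log2 fold change was 6.04 ± 0.15 (SE) with an adjusted p of 1.5e-43 by edgeR's quasi-likelihood test, and it was higher in 34 of 36 libraries. Myog (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548) was higher by 5.05 ± 0.15, Actn2 by 5.31 ± 0.15 in 36 of 36 libraries and Mylpf by 5.16 ± 0.20 in 36 of 36. Tnnc2 (5.13 ± 0.17) overlaps Ube2c, so its level is uncertain. Log2 fold changes were 4.36 for Tnni1, 3.61 for Ttn, 4.06 for Ctss, 2.65 for Lyz2 and 3.12 for Sox10, against -0.17 for Cald1, -0.24 for Tagln, -0.21 for Prrx1, -0.31 for Thy1 and -1.24 for the protease Mmp3. Of 16532 genes tested, 798 were higher and 424 lower. Of 731 genes higher with Mef2c and also tested with Myod1, 549 were higher with Myod1 too. Each factor was fitted alone, so these comparisons do not separate Mef2c from Myod1.

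Of the skeletal muscle list, 26 of 27 genes were higher with Mef2c (26 adjusted over the list alone; camera adjusted p = 3e-93, and 4.9e-08 with an estimated correlation). Of the cardiomyocyte list, which shares sarcomere genes with skeletal muscle, 19 of 30 were higher (22 adjusted over the list alone; 4e-36, and 4.7e-05 with an estimated correlation). Macrophage genes were higher for 11 of 15 (13 adjusted over the list alone; 3.3e-11, but 0.056 with an estimated correlation) and fibroblast genes lower for 8 of 25 (12 lower and 1 higher adjusted over the list alone; 3.6e-07, but 0.056 with an estimated correlation). Smooth muscle genes were lower for 4 of 20 and higher for 1 (6 and 1 adjusted over the list alone; 0.0020, but 0.33 with an estimated correlation). Their sum was lower in 24 of 36 libraries (permutation adjusted p = 0.0474), but did not pass without the cells of other types (0.34). The summed skeletal muscle list stood at 2244 ± 1514 against 485 ± 186 CPM, higher in 35 of 36 libraries, a log2 ratio of 2.07 (permutation adjusted p = 0.000293). The ratio was 2.04 in JD, 2.15 in PZ47-PZ48 and 1.97 in PZ58, and 1.93 and 2.12 in the high and low read class. Without skeletal muscle-like, mesothelial-like, glial-like and macrophage-like cells it was 0.13 (adjusted p = 0.48), the cardiomyocyte ratio was 0.11 in place of 1.51, and 161 genes passed the threshold, 151 of them among those called with all cells. Glial genes were higher for 4 of 13 (4 adjusted over the list alone; 0.0069, but 0.15 with an estimated correlation) and S phase genes lower for 2 of 20 (3 adjusted over the list alone; 7.6e-05, but 0.34). Neither sum passed (adjusted p = 0.551 and 0.364). Mitochondrially encoded genes were higher for 3 of 11 (6 adjusted over the list alone; camera adjusted p = 0.0080, but 0.34 with an estimated correlation), their sum by a log2 ratio of 0.11 in 26 of 36 libraries (permutation adjusted p = 0.0055).

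Gata6 encodes a zinc finger factor of mesoderm and endoderm. Cells with it were richer in genes of the mesothelium, the lining of body cavities from which the epicardium derives, among them the uroplakins Upk3b and Upk1b, the membrane protein Lrrn4 and the glycoprotein Gpm6a. They also held more of the atrial myosin Myh6, of the matrix genes Dcn and Lum and of the lipase Lpl, and less of the receptor Il1rl1, the chemokine Cxcl14, the homeobox gene Msx2 and the mitotic gene Birc5. Upk3b (ENSMUSG00000042985, chromosome 5, 136038496 to 136046487) stood at 46.3 ± 33.9 CPM in 2001 cells with Gata6 and 3.13 ± 7.53 CPM in matched cells, a log2 fold change of 4.49 ± 0.27 (edgeR adjusted p = 4.7e-20, higher in 33 of 36 libraries). Changes were 3.87 for Upk1b, 3.65 for Lrrn4, 3.51 for Gpm6a, 3.04 for Myh6, 0.91 for Dcn, 0.84 for Lum and 0.83 for Lpl, and -1.24 for Il1rl1, -1.07 for Cxcl14, -1.04 for Msx2, -0.45 for Birc5 and -0.30 for Prrx1. Sult1e1 and Muc16 had 0 counts in the matched cells without Gata6 and are given without a fold. In all, 790 genes were higher and 488 lower.

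Of the mesothelial list, 16 of 19 genes were higher with Gata6 (16 adjusted over the list alone; camera adjusted p = 2.4e-36, and 2.9e-07 with an estimated correlation). The summed list stood at 1103 ± 321 against 551 ± 162 CPM, higher in 36 of 36 libraries, a log2 ratio of 0.99 (permutation adjusted p = 0.000293). In JD it stood at 1111 against 498 CPM, and the log2 ratio was 0.87 and 1.07 in PZ47-PZ48 and PZ58, 1.04 and 0.98 in the high and low read class, and 0.63 without the cells of other types (adjusted p = 0.000432). Cardiomyocyte genes were higher for 11 of 30 (13 higher and 1 lower adjusted over the list alone; 3.8e-09, but 0.056 with an estimated correlation). Genes of G2 and M phase were lower for 8 of 24 (19 adjusted over the list alone; 4.6e-10, but 0.26 with an estimated correlation), and their sum did not pass the permutation test (adjusted p = 0.156). Beside Dcn and Lum, most of the called fibroblast genes were lower, 11 of 25 against 6 higher (11 and 7 adjusted over the list alone; 0.077, and 0.39 with an estimated correlation). Skeletal muscle genes were higher for 2 of 27 (4 adjusted over the list alone; 0.00034, but 0.36 with an estimated correlation) and mitochondrially encoded genes lower for 1 of 10 (3 adjusted over the list alone; 0.00039, but 0.26). Neither sum passed (adjusted p = 0.25 and 0.364).

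Hand2, a basic helix-loop-helix factor of the heart and limb, went in part with the same genes as Gata6. Of its 571 higher genes, 253 were also higher with Gata6, and 61 genes were lower with both. The comparisons are not separate, as 399 cells held both factors, so this overlap is no test of shared targets. Independent lists would share 29.5 higher and 11.0 lower genes. Overlap is not particular to this pair, as Gata6 shared 211 higher genes with Gata4, against 21.3 from independent lists. Cells with Hand2 held more of the tachykinin gene Tac2 and of the mesothelial genes Upk1b, Upk3b, Msln and Wt1. The cartilage matrix gene Comp and the small heat shock gene Hspb7 were higher as well. Muscle genes (Myh3, Ankrd2) and genes induced by BMP or TGF-beta (Id3, Ccn2) were lower. Tac2 (ENSMUSG00000025400, chromosome 10, 127724478 to 127731768) stood at 26.9 ± 33.6 CPM in the 910 cells with Hand2 and at 8.41 ± 40.2 CPM in matched cells, with a log2 fold change of 3.13 ± 0.40 (edgeR adjusted p = 7.4e-08, higher in 27 of 36 libraries). The SD in the matched cells far exceeds the mean, so a few libraries carry that mean. The fold change is that of the fit and not the ratio of these means. Changes were 2.81 for Upk1b, 2.87 for Upk3b, 2.10 for Msln, 1.65 for Wt1, 2.42 for Comp and 0.95 for Hspb7, and -2.95 for Myh3, -3.09 for Ankrd2, -0.50 for Id3 and -0.54 for Ccn2. ENSMUSG00000100348, which has no position in the annotation used, had 470 counts in 349 cells, and all 349 also held Hand2. In all, 571 genes were higher and 341 lower.

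Of the mesothelial list, 12 of 19 genes were higher with Hand2 (14 adjusted over the list alone; camera adjusted p = 1.1e-20, and 5.4e-06 with an estimated correlation). Retinoic acid targets were higher for 4 of 11 (4 adjusted over the list alone; 0.0013, and 0.023 with an estimated correlation), though their sum did not pass the permutation test (adjusted p = 0.816), and BMP and TGF-beta targets went down for 4 of 14 and up for 1 (7 and 3 adjusted over the list alone; 0.0042, and 0.029 with an estimated correlation). Skeletal muscle genes were lower for 17 of 27 (22 adjusted over the list alone; 6.8e-17, but 0.056 with an estimated correlation). Summed mesothelial expression was higher in 31 of 36 libraries, with a log2 ratio of 0.65 (0.46, 0.78 and 0.84 in the 3 series), and 0.84 and 0.60 in the high and low read class. Without the cells of other types it was 0.16 (adjusted p = 0.48). The skeletal muscle ratio of -1.15 (higher in 7 of 36 libraries, permutation adjusted p = 0.0039) likewise became -0.30 (adjusted p = 0.27), and the log2 fold change of Myh3 with Hand2 became 0.65 (adjusted p = 0.60). That of the BMP and TGF-beta list was -0.29 with all cells and -0.28 without them, lower in 33 of 36 libraries in the latter. Macrophage genes were lower for 2 of 14 (8 adjusted over the list alone; 0.0010, but 0.33 with an estimated correlation) and smooth muscle genes for 2 of 20, with 1 higher (3 and 2 adjusted over the list alone; 0.0063, but 0.41). Neither sum passed (adjusted p = 0.62 and 0.116). Of 7 mitochondrially encoded genes 0 were called (0 adjusted over the list alone). Camera gave 0.026, direction down, but 0.46 with an estimated correlation. Their sum did not pass (adjusted p = 0.421).

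Mesp1, a regulator of early cardiac mesoderm, and Foxn4, a forkhead factor, were modelled next. Of 14028 genes tested with each, 271 were higher with both and 235 lower with both, but 91 cells held both factors, so the comparisons are not separate. Independent lists would share 38.4 and 23.9. Mesp1 shared more genes with Myod1, 361 higher and 283 lower (79.9 and 38.5 from independent lists), so overlap is not particular to Foxn4. With Mesp1 the transcriptional coregulator Cited1, the peptidase inhibitor Spink4, the Wnt antagonist Sost, the cardiac myosin binding protein Mybpc3 and the lipase Lpl were higher, and the Wnt modulator Sfrp2 and the proteoglycan Bgn lower. With Foxn4 the epithelial keratins Krt18 and Krt8 were higher, with Zcchc12 and the chemokine Ppbp, while fibrillin Fbn1, the kinase Plk2 and the endothelial gene Emcn were lower. Cited1 (ENSMUSG00000051159, chromosome X, 102247381 to 102252181) rose by 4.59 ± 0.35 on the log2 scale with Mesp1 (503 cells, 28 of 36 libraries, edgeR adjusted p = 1.1e-12). Spink4 changed by 4.38, Sost by 4.36, Mybpc3 by 2.62, Lpl by 1.59, Sfrp2 by -2.92 and Bgn by -0.67. Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027) stood at 1000.3 ± 852 CPM in the 452 cells with Foxn4 and at 101 ± 149 CPM in matched cells, a log2 fold change of 3.25 ± 0.32 (adjusted p = 1.5e-10, higher in 33 of 35 libraries). Zcchc12 (ENSMUSG00000036699, chromosome X, 36195904 to 36199158) changed by 4.75 ± 0.37, Ppbp by 4.53, Krt8 by 2.27, Fbn1 by -0.81, Plk2 by -0.95 and Emcn by -2.67. Counts of genes past the threshold were 856 higher and 629 lower with Mesp1, and 666 and 536 with Foxn4. Fibroblast genes were lower with Foxn4 for 12 of 25 (15 adjusted over the list alone; camera adjusted p = 1e-14, and 0.013 with an estimated correlation), with log2 ratios of the summed list of -0.26, -0.19 and -0.26 in the 3 series. In the same comparison the sum of mitochondrially encoded genes was higher by a log2 ratio of 0.25 (permutation adjusted p = 0.013), with 0 of 7 genes called over all genes tested (6 higher adjusted over the list alone; camera adjusted p = 2.5e-05, but 0.20 with an estimated correlation). With Mesp1 their sum was higher by 0.20 (adjusted p = 0.0251), with 0 of 7 called (0 adjusted over the list alone; camera 0.00076, but 0.26 with an estimated correlation). The mesothelial list did not move as a set with Foxn4: 2 of 17 genes were higher and 2 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.55, and 0.80 with an estimated correlation), with a median log2 fold change of -0.33. Its summed expression was nonetheless higher, at 1591 ± 996 against 661 ± 346 CPM (32 of 35 libraries, log2 ratio 1.13), and Krt18 is a member. Cardiomyocyte genes were higher with Mesp1 for 12 of 27 (18 adjusted over the list alone; 7.8e-08, but 0.20 with an estimated correlation); the summed list missed the threshold over all cells (log2 ratio 0.98, adjusted p = 0.069) and passed it without the cells of other types (1.08, adjusted p = 0.0019). Beside them, fibroblast genes were lower with Mesp1 for 8 of 25 and higher for 3 (11 and 3 adjusted over the list alone; 1.6e-05, but 0.10 with an estimated correlation), skeletal muscle genes higher for 7 of 26 (7 adjusted over the list alone; 0.0010, but 0.45) and mesothelial genes lower for 3 of 18 (5 adjusted over the list alone; 0.0081, but 0.30). None of these sums passed (adjusted p = 0.532, 0.898 and 0.601). With Foxn4, skeletal muscle genes were higher for 4 of 26 (4 adjusted over the list alone; 0.011, but 0.51 with an estimated correlation) and cardiomyocyte genes for 1 of 29 (3 adjusted over the list alone; 0.042, but 0.46). Neither sum passed (adjusted p = 0.958 and 0.721).

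Tbx5, Nkx2-5 and Isl1 are regulators of heart development. With Tbx5 the atrial genes Myh6, Myl7 and Nppa were higher and the cartilage collagen Col2a1 lower. With Nkx2-5 the TGF-beta responsive gene Ccn2 was lower and Myl7 and Mybpc3 higher, and with Isl1 the relaxin receptor Rxfp1 was higher. Myh6 (ENSMUSG00000040752, chromosome 14, 54941921 to 54966927) rose by 3.95 ± 0.61 with Tbx5, but was higher in only 10 of 35 libraries and lower in 2, as most had no count. Myl7 changed by 3.58 with Tbx5, but was higher in only 9 of 35 libraries and lower in 6 (26.3 ± 89.7 CPM with Tbx5), so a few libraries carry the fold, and it changed by -0.35 without the cells of other types. Nppa changed by 2.66, Krt18 by 1.91, Col2a1 by -1.84 and Id1 by -0.67 with Tbx5. Nppa stood at 43.4 ± 88.0 against 4.54 ± 7.75 CPM, higher in 18 of 35 libraries and lower in 9. Gm13054 had nearly the same values (42.0 ± 84.7 against 4.34 ± 7.41 CPM), so the level of Nppa is uncertain. Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683) stood at 304 ± 173 CPM in cells with Nkx2-5 and 556 ± 280.4 CPM in matched cells, a log2 fold change of -0.94 ± 0.13 (edgeR adjusted p = 2.6e-06, lower in 28 of 35 libraries). Plk2 changed by -0.90, Gdf15 by 1.55, Myl7 by 3.40 (higher in only 10 of 35 libraries) and Mybpc3 by 2.77 with Nkx2-5. Rxfp1 (ENSMUSG00000034009, chromosome 3, 79641611 to 79737880) rose by 3.03 ± 0.27 with Isl1 in 31 of 36 libraries (edgeR adjusted p = 5.6e-13), beside Gm26880 at 2.81. The counts of genes higher and lower were 92 and 27 with Tbx5 (447 cells), 272 and 267 with Nkx2-5 (398 cells) and 78 and 36 with Isl1 (397 cells). With Tbx5 and Isl1 these counts include genes carried by few libraries, down to 1. BMP and TGF-beta targets were lower with Nkx2-5 for 6 of 14 (6 adjusted over the list alone; camera adjusted p = 5.1e-08, and 0.00021 with an estimated correlation), and their summed log2 ratio was -0.47, with -0.54, -0.41 and -0.41 in the series and -0.53 and -0.45 in the classes. Markers of cell types were lower with Nkx2-5 as well, for 4 of 20 smooth muscle genes (8 lower and 1 higher adjusted over the list alone; 5.4e-07, but 0.16 with an estimated correlation) and 8 of 25 fibroblast genes (8 lower and 1 higher adjusted over the list alone; 3e-05, but 0.056), though neither sum passed the permutation test (adjusted p = 0.132 and 0.958). Cardiomyocyte genes were higher for 3 of 30 with Tbx5 (5 adjusted over the list alone; 0.00093, but 0.31 with an estimated correlation), for 6 of 28 and lower for 1 with Nkx2-5 (8 and 1 adjusted over the list alone; 0.00088, but 0.34 with an estimated correlation) and for 1 of 28 with Isl1 (5 adjusted over the list alone; 0.00039, but 0.30 with an estimated correlation). The summed list passed the permutation test with none of the 3 (adjusted p = 0.951, 0.617 and 0.409). Markers of other cells and of S phase were also called as sets by camera at the preset correlation alone. With Tbx5 these were smooth muscle genes, lower for 1 of 20 and higher for 2 (4 and 2 adjusted over the list alone; direction down, 0.0013, but 0.31 with an estimated correlation). With Isl1, no gene of the smooth muscle, fibroblast and S phase lists was called over all genes tested. Adjusted over the list alone, 1 smooth muscle gene was lower and 2 higher, 5 fibroblast genes were lower and 1 S phase gene was lower. The camera adjusted p, direction down, was 0.00034, 7.3e-05 and 5.6e-07 (but 0.22, 0.18 and 0.15 with an estimated correlation). Skeletal muscle genes were higher with Isl1 for 1 of 27 (2 adjusted over the list alone; 0.0055, but 0.51). None of these sums passed (adjusted p = 0.184 with Tbx5, and 0.138, 0.424, 0.35 and 0.551 with Isl1). Of 7 mitochondrially encoded genes, 0 were called with Tbx5 and 0 with Nkx2-5 (0 adjusted over the list alone for both), and 1 was higher with Isl1 (2 adjusted over the list alone). Camera gave 0.043, 0.00088 and 0.00065, direction up, but 0.46, 0.26 and 0.26 with an estimated correlation. Their sum passed with Isl1 alone (log2 ratio 0.14, adjusted p = 0.0113).

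Myod1, Myocd and Gata4 were modelled after their numbers of cells had been seen. Myod1, which can turn fibroblasts into muscle, went with the muscle genes Ankrd2, Actc1, Mylpf, Ttn and Tnnt1 and with the fusion gene Mymk, and with less of the fibroblast genes Lox and Vim. Myocd, a coactivator of smooth and cardiac muscle genes, went with Myh6, Myl7, Mybpc3, Smpx, Ankrd1, Myl9 and Acta2. Gata4, a cardiac zinc finger factor, went with Mybpc3 and Tnnt2 and with the mesothelial Upk1b and Upk3b. Mymk (ENSMUSG00000009214, chromosome 2, 27061636 to 27072179) rose by 6.47 ± 0.21 with Myod1 (350 cells, 32 of 34 libraries, edgeR adjusted p = 9e-40), Ankrd2 by 7.13, Actc1 by 6.96, Mylpf by 6.78, Ttn by 6.14 and Tnnt1 by 5.74. Lox changed by -0.92 and Vim by -0.51. Ankrd1 (ENSMUSG00000024803, chromosome 19, 36111961 to 36120099) rose by 2.86 ± 0.27 with Myocd (260 cells, 32 of 34 libraries, adjusted p = 2.1e-10). Smpx rose by 4.40, Mybpc3 by 4.77, Myh6 by 4.96 and Myl7 by 4.87 (higher in only 9 and 10 of 34 libraries) and Myl9 by 1.22, Acta2 went from 4683 ± 2155 to 8668 ± 2789 CPM, and Pdgfra changed by -1.92. Mybpc3 (ENSMUSG00000002100, chromosome 2, 91118144 to 91136516) rose by 5.06 ± 0.46 with Gata4 (204 cells, 20 of 29 libraries, adjusted p = 4.7e-09), Tnnt2 by 3.16, Upk1b by 4.32 and Upk3b by 4.30, and Prrx1 changed by -0.74. The counts of genes higher and lower were 1380 and 846 with Myod1, 511 and 330 with Myocd, and 387 and 143 with Gata4.

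With Myod1, all 27 skeletal muscle genes were higher (27 adjusted over the list alone) and 25 of 28 cardiomyocyte genes (26 adjusted over the list alone), both with an adjusted p of 6.5e-06 with an estimated correlation. Fibroblast genes were lower for 16 of 25 (20 adjusted over the list alone; 0.019 with an estimated correlation), and all 7 mitochondrially encoded genes tested were higher (7 adjusted over the list alone; 0.035), their sum by a log2 ratio of 0.45 in 32 of 34 libraries. With Myocd, 18 of 30 cardiomyocyte genes (26 adjusted over the list alone; 0.00011 with an estimated correlation) and 16 of 20 smooth muscle genes were higher (17 adjusted over the list alone; 0.0011), and 12 of 25 fibroblast genes lower (17 lower and 2 higher adjusted over the list alone; 0.00071). With Gata4, 15 of 24 cardiomyocyte genes (19 adjusted over the list alone; 0.0065) and 13 of 18 mesothelial genes were higher (13 adjusted over the list alone; 0.00035), fibroblast genes lower for 6 of 25 and higher for 2 (13 and 2 adjusted over the list alone; 0.037), though their sum did not pass (adjusted p = 0.318), and BMP and TGF-beta targets lower for 1 of 14 (1 adjusted over the list alone; 0.0030). Skeletal muscle genes were higher for 11 of 26 with Myocd (20 adjusted over the list alone; adjusted p = 0.092 with an estimated correlation) and for 9 of 25 with Gata4 (14 adjusted over the list alone; 0.28 with an estimated correlation), where the summed list did not pass the permutation test (adjusted p = 0.722). Without the cells of other types the summed skeletal muscle ratio with Myod1 went from 4.33 to 1.61 (adjusted p = 0.000432), while the cardiomyocyte ratio was 2.16 and 2.11 with Myocd and 2.03 and 2.01 with Gata4. Smooth muscle genes were higher with Myocd in 31 of 34 libraries (log2 ratio 0.70). Of 7 mitochondrially encoded genes 0 were called with Myocd (0 adjusted over the list alone; camera adjusted p = 0.0014, direction up, but 0.30 with an estimated correlation). Their sum did not pass (adjusted p = 0.308). Mesothelial genes were lower with Myocd for 2 of 17 (3 adjusted over the list alone; 0.047, but 0.38 with an estimated correlation) and G2 and M phase genes with Gata4 for 1 of 24 (10 adjusted over the list alone; 2e-10, but 0.19). Neither sum passed (adjusted p = 0.848 and 0.121).

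**Figure D2:**
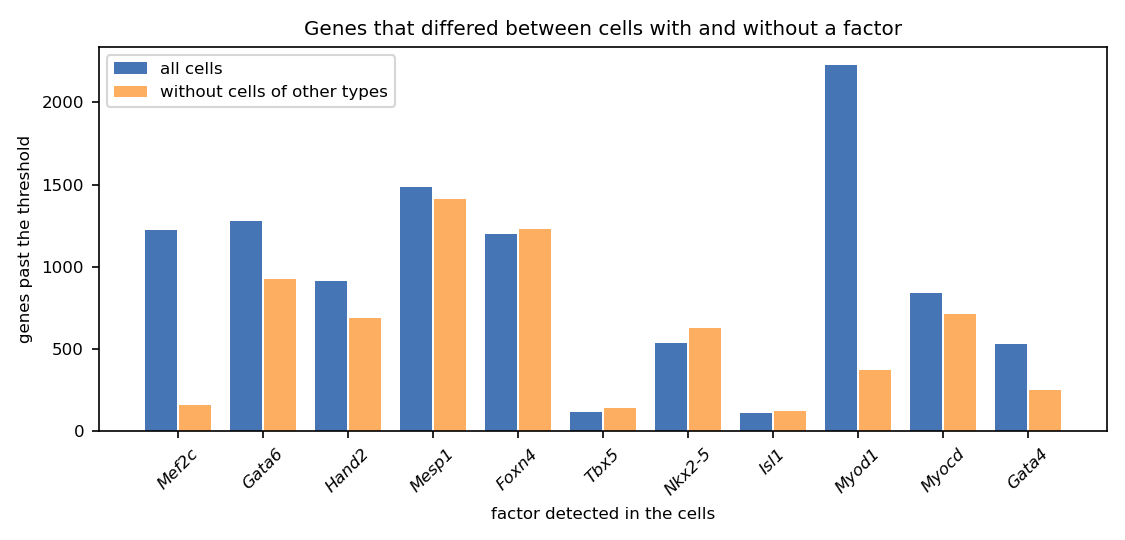
Number of genes that differed between cells with and without each factor (edgeR, adjusted p under 0.05), with all cells and without skeletal muscle-like, mesothelial-like, glial-like and macrophage-like cells. The number with Mef2c goes from 1222 to 161 and that with Myod1 from 2226 to 374, while those with Mesp1 and Foxn4 are 1485 and 1414, and 1202 and 1233.

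Across 41 factors and 20 lists, 143 of 820 permutation tests passed the threshold, 71 of them higher and 72 lower. These tests are of sums, which a few genes can carry. Camera instead tests whether the genes of a list, each counted alike, rank above or below all other genes. It is a test of the set and not of single genes, and is what gene by gene stands for below. With the 11 modelled factors 49 sums passed. For these, camera passed 35 in the same direction and 17 with an estimated correlation. Lists of muscle divided the factors. The cardiomyocyte list was higher with 10 factors (Myod1, Myocd, Gata4, Mef2c, Smarcd3, Mef2a, Cdkn1a, Mef2b, Mef2d and Gata6) and lower with 6, the skeletal muscle list higher with 7 and lower with 10, Hand2 and Lbh among the latter, and the smooth muscle list higher with Myocd and Lbh and lower with 7. The summed mesothelial list was higher with Foxn4, Gata4, Gata6, Hand2, Tbx5, Tbx2 and Lbh and lower with 2. Gene by gene, it did not pass with Foxn4 (camera adjusted p = 0.55, direction down) or with Tbx5, where 1 of 19 genes was higher (2 adjusted over the list alone; camera adjusted p = 0.22, and 0.62 with an estimated correlation). The summed endothelial list was higher with 2 and lower with 3, but gene by gene camera did not pass with Hand2 (adjusted p = 0.17) or Myod1 (0.085), and passed with Mesp1 and Foxn4 only at the preset correlation (0.056 for both with an estimated one). Among sums, the macrophage list was higher with Mef2a and Mef2c and lower with Smarcd3, and the fibroblast list higher with Lbh and Shox2 and lower with 7. The glial sum was lower with 2 factors and higher with 0, and the chondrocyte sum lower with 6 and higher with 0, though not gene by gene with Myod1, the modelled factor among the 6 (camera adjusted p = 0.59). The keratinocyte sum was higher with 6 and lower with 2. Gene by gene, camera did not pass with Hand2 (adjusted p = 0.080, median log2 fold change -0.07) or Nkx2-5 (0.16, 3 genes tested), and with Gata6 it passed at the preset correlation (0.028) but not at an estimated one (0.17). With Gata6 the list also passed with fry, which does not set a list against other genes (adjusted p = 0.0050). The summed adipocyte list was higher with 6 and lower with Isl1, but gene by gene it did not pass with 4 of the 6. With Mesp1 1 of 7 genes was higher (1 adjusted over the list alone; camera adjusted p = 0.84, and 0.87 with an estimated correlation) and the median log2 fold change was -0.36, and with Foxn4 1 of 7 was higher and 1 lower (1 and 3 adjusted over the list alone; 0.73, direction down, and 0.80 with an estimated correlation). The camera adjusted p was 0.13 with Gata6 and 0.066 with Mef2c, though fry passed with both (adjusted p = 0.024 and 0.0079). With Myod1 and Isl1 the camera adjusted p was just under the threshold (0.04998 and 0.045, the latter with 0 of 7 genes called and 1 lower adjusted over the list alone) but 0.095 and 0.15 with an estimated correlation. None of the modelled factors kept it there. Meis1, the other of the 6, was not tested gene by gene. The sum of S phase genes was higher with 5 and lower with 3, and that of G2 and M phase genes higher with 5 and lower with 4. The sum of the p53 response was higher with 7, among them its target Cdkn1a, and lower with Myod1 (camera adjusted p = 0.0059, but 0.18 with an estimated correlation). The sum of BMP and TGF-beta targets was higher with Lbh and lower with 8 factors, Nkx2-5, Hand2 and Gata4 among them; gene by gene it did not pass with Myod1 (camera adjusted p = 0.059), nor with Gata6 and Tbx5 at an estimated correlation (0.22 and 0.056). The sum of retinoic acid targets was higher with 2 and lower with 3, but gene by gene camera passed neither with Mesp1, among the 2 (0.099), nor with Mef2c, among the 3 (0.13). Fry passed with Mef2c (adjusted p = 0.029, direction down). The sum of Notch targets was higher with Rxra alone. That of mitochondrially encoded genes was higher with 6 and lower with 6, and of the 5 modelled factors among them, all higher, only Myod1 passed with an estimated correlation. The interferon and immediate early sums passed with none. Gene by gene, camera passed the interferon list at the preset correlation with Myocd (5 of 20 lower, 7 adjusted over the list alone; adjusted p = 7.5e-05), Mesp1 (4 of 20 lower, 4 adjusted over the list alone; 0.0030), Foxn4 (1 of 20 higher, 1 adjusted over the list alone; 0.0040) and Gata6 (2 of 21 higher, 3 adjusted over the list alone; 0.038). With an estimated one it passed with none of them (0.19, 0.36, 0.31 and 0.52). At an unadjusted p under 0.05, 234 tests passed. Within JD, 38 tests passed and within PZ47-PZ48 50. Within PZ58 the permutation test passed none (57 unadjusted), where 6 libraries allow no p under 0.03125. Within the high read class it passed none (132 unadjusted), and the smallest p, 0.00196, is about the lowest that 10 libraries allow. Without the cells of other types 99 tests passed, 56 higher and 43 lower. With Mef2c the log2 ratio of the skeletal muscle list was then 0.13, against 2.07 with all cells, so muscle sums can rest on the cells of other types. Values in that setting are not given here for factors outside the 11 modelled ones.

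**Figure D3:**
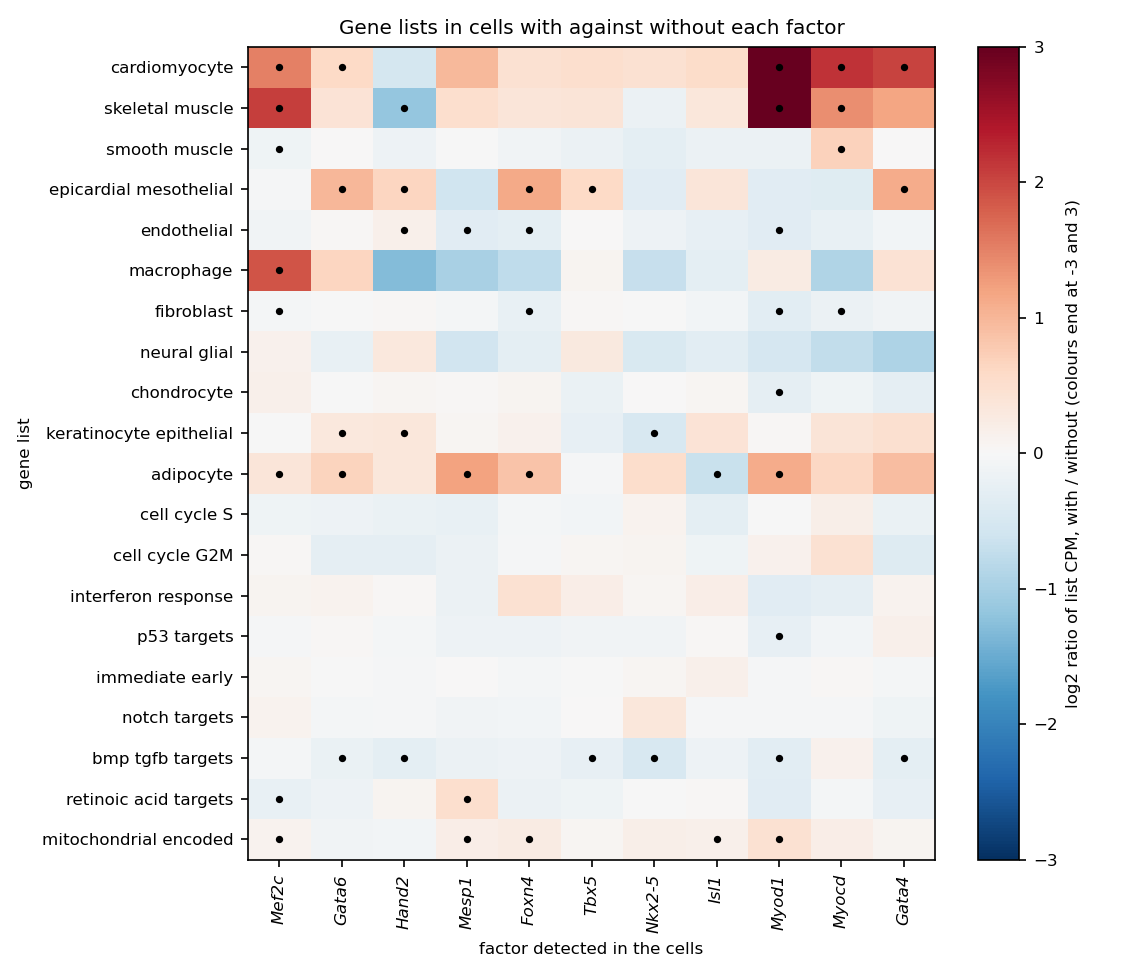
Log2 ratio of the summed CPM of each of 20 gene lists in cells with against cells without each of 11 factors, with dots where the permutation adjusted p is under 0.05. Skeletal muscle and cardiomyocyte genes are highest with Myod1 (4.33 and 3.79) and the mesothelial list is higher with Gata6 (0.99), Hand2 (0.65) and Gata4 (1.12). Its sum is also higher with Foxn4 (1.13) and Tbx5 (0.59), where the genes of the list did not shift as a set (camera adjusted p = 0.55 and 0.22).

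Gata4, Mef2c and Tbx5 are together known to drive fibroblasts towards cardiomyocytes, and the next comparison asked whether muscle genes rose with their number. The summed cardiomyocyte and skeletal muscle lists were higher in cells with 1 of the factors than in cells with none, though without the cells of other types only the former passed. Of all cells, 5929 held none, 2388 held 1, 236 held 2 and 10 held 3. As Mef2c was found in 2230 cells, most cells with 1 factor held Mef2c. Over all cells, the step from 0 to 1 therefore largely restates the comparison for Mef2c. Between 0 and 1, the cardiomyocyte list rose from 883 ± 305 to 2931 ± 1604 CPM (log2 ratio 1.63, higher in 35 of 36 libraries) and the skeletal muscle list from 475 ± 180 to 2050 ± 1488 CPM (log2 ratio 1.96, 35 of 36), each with a permutation adjusted p of 2.67e-05. Smooth muscle genes fell (log2 ratio -0.12, adjusted p = 0.0276) and so did fibroblast genes (-0.06, higher in 6 of 36 libraries), but neither passed without the cells of other types (adjusted p = 0.195 for both). Smooth muscle genes also did not pass against unmatched cells (0.112) or without the 5% of cells with the most counts (0.113). The cardiomyocyte ratio was 1.63 in JD, 1.67 in PZ47-PZ48 and 1.55 in PZ58. Without the cells of other types it was 0.48 (adjusted p = 0.00176), and the skeletal muscle ratio was 0.18 (0.284). In that setting the cardiomyocyte ratio was smaller with Mef2c and larger with Gata4, so this rise does not merely restate the comparison for Mef2c. Which of the factors carries it was not tested. Between 1 and 2 or 3 factors (30 libraries, 237 cells), no list passed the permutation test. The cardiomyocyte list differed by 338 CPM on average (adjusted p = 0.669), higher in 20 of 30 libraries with a pooled log2 ratio of 0.68, and the skeletal muscle list by -338 CPM (0.669) although it was higher in 21 of 30 libraries and its pooled log2 ratio was 0.16.

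Clusters of cells, made without the factor genes, were compared next for the factors their cells held. Of 15 clusters, 5 could be named from markers. They were smooth muscle-like (250 cells, led by Actg2 and Myh11), mesothelial-like (200, Upk1b and Upk3b), skeletal muscle-like (151, Mylpf and Myh3), glial-like (87, Ngfr and Cdh19) and macrophage-like cells (27, Lyz2 and Ctss). The size of the smooth muscle-like cluster depended on the setting, with 780 cells at resolution 1.0, 1186 after centring within read class and no cluster of that name at resolution 0.3. Clusters 3 and 4, with 1576 and 630 cells, held cells of the high read class alone and were led by ribosomal genes or by Kpna2. Skeletal muscle-like cells held Mef2c in 91.6 ± 17.2% and Myod1 in 65.2 ± 20.3% (SD over libraries), against 22.7 ± 21.6% and 4.68 ± 9.86% of depth-matched other cells, both higher in 24 of 25 libraries. Mesothelial-like cells held Gata6 in 77.3 ± 18.6% against 14.9 ± 12.9% (28 of 28 libraries), Hand2 in 48.5% against 9.62% and Gata4 in 14.1% against 3.10%. Mef2c was found in 63.3 ± 22.8% of glial-like cells against 16.0 ± 21.1% (12 of 13 libraries). Myocd was found in 7.78% of smooth muscle-like cells against 1.46%, and Lbh in 90.8% against 74.3%. A cluster led by Krt18, Krt8 and Chodl (235 cells) held Foxn4 in 41.8 ± 18.0% against 2.87 ± 6.06% (25 of 26 libraries) and Mesp1 in 30.6% against 5.93%. One led by Tac2 and Nnat (205 cells) held Hand2 in 60.3 ± 19.0% against 8.75 ± 12.1% (22 of 22 libraries), Gata6 in 45.3% against 24.4% and Hand1 in 9.56% against 0.552%. Free RNA, which would reach cells of like depth in a library alike, is thus not the whole source of the counts of Myod1, Gata6, Foxn4 and Hand2. In all, 73 of 574 tests of a factor in a cluster passed (38 higher, 35 lower; permutation test, adjusted p of 0.00052 for Mef2c, Myod1, Gata6, Hand2 and Foxn4 in the clusters named with them, 0.0090 for Mef2c in glial-like cells and 0.045 for Myocd). After centring within read class there were 14 clusters and 100 of 533 tests passed. The skeletal muscle-like cells then held Mef2c in 91.8% and Myod1 in 65.2%, the smooth muscle-like cells Myocd in 8.17% against 2.62% (adjusted p = 0.000888), the Krt18 cluster (318 cells) Foxn4 in 37.7% against 3.00%, and the Tac2 cluster (311 cells) Hand2 in 56.2% against 7.64%. Within the high read class alone the permutation test passed none of 410 (56 unadjusted), and within the low class 82 of 492. The smallest p in the high class, 0.00196, is about the lowest that its 10 libraries allow. None could pass after adjustment unless many tests reached it.

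**Figure D4:**
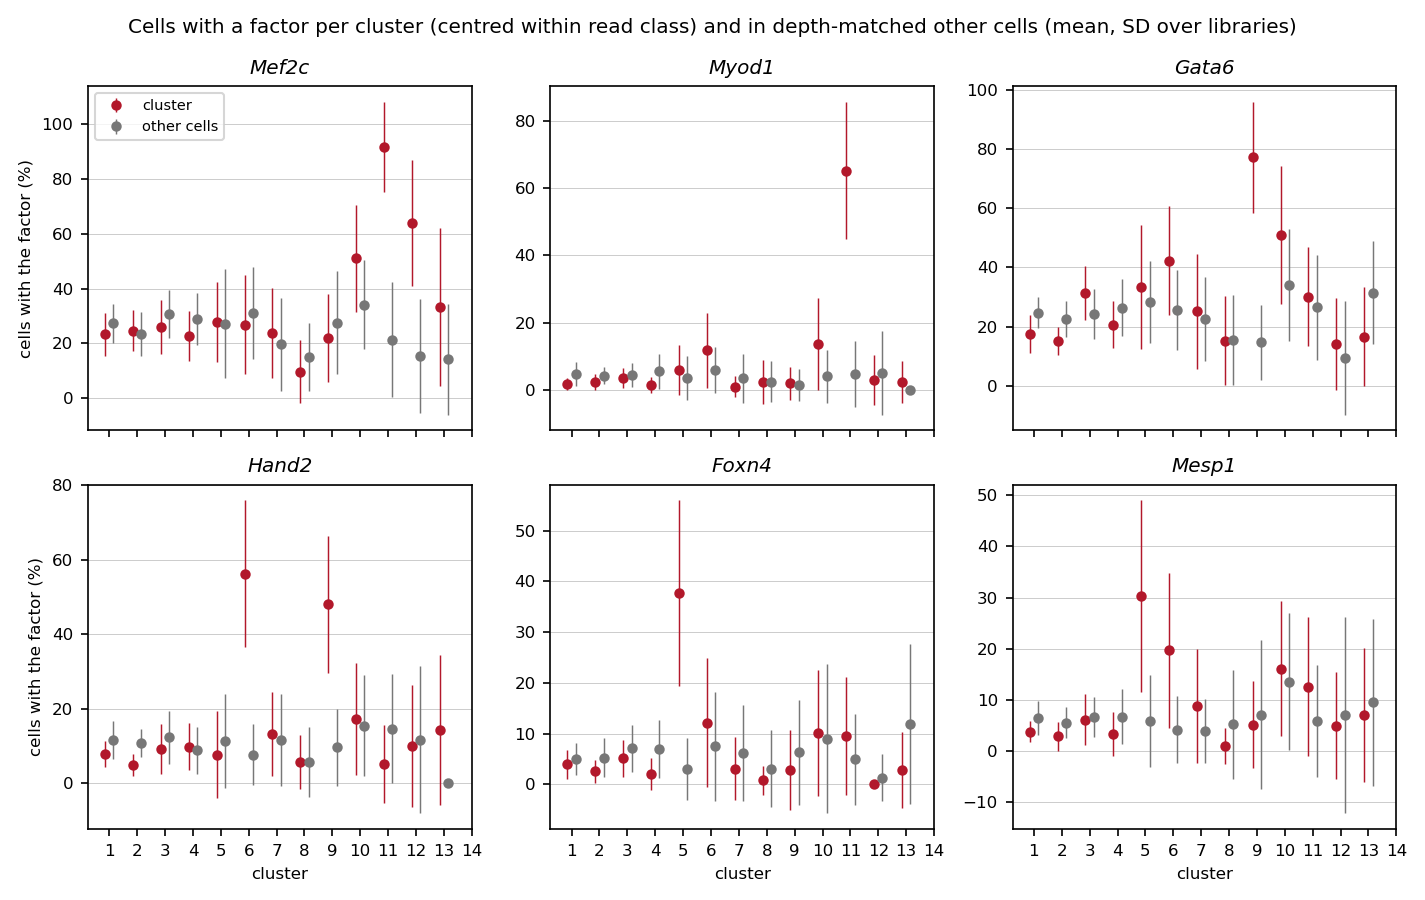
Percent of cells with 6 factors in each cluster made after centring within read class (red) and in depth-matched other cells of the same libraries (grey), as mean and SD over libraries; cluster 14 was not tested. Mef2c and Myod1 peak in cluster 11 (skeletal muscle-like, 91.8% and 65.2%), Gata6 in cluster 9 (mesothelial-like), Foxn4 in cluster 5 (37.7%) and Hand2 in cluster 6 (56.2%).

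Factor pairs were last compared with the numbers that independence within library and depth stratum gives. Mesp1 and Foxn4 were found together in 91 cells, 2.65 times the number from independence (31 of 36 libraries above it), Mesp1 and Nkx2-5 in 80 cells (2.64 times, 33 of 36) and Foxn4 and Nkx2-5 in 64 cells (2.24 times, 27 of 36). Gata6 and Hand2, both frequent in mesothelial-like cells, shared 399 cells (1.61 times, 36 of 36), and Hand2 and Mesp1 119 (1.84 times, 30 of 36). Of 28 pairs, 22 passed the threshold, all above independence. Permutation adjusted p-values were 4.67e-05 for the first 4 pairs and 8e-05 for Hand2 with Mesp1. Mef2c and Hand2 were found together in 272 cells, 0.979 times the number from independence (adjusted p = 0.736). For Mesp1 and Foxn4, JD held 32 cells with both against 12.8 from independence, and the ratio was 2.76 in PZ47-PZ48 and 2.66 in PZ58, and 2.78 and 2.62 in the high and low read class. Pairs of a factor with genes outside the pool had a median ratio of 1.11, with a 95th percentile of 1.52. Only 9 of the 28 factor pairs lay above it, so for the others, some of which passed the permutation test, the excess is not told from residual depth.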

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

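Limma-voom, all barcode copies kept, thinning to 1500 counts, each read class alone, centring within read class, the setting without cells of other types, and every setting for Myod1, Myocd and Gata4 were chosen after the data had been seen. Keeping all deposited cells, or only those with at least 1000 counts, moved nothing, since every cell had at least 1541 counts, and so tests nothing. Of 5715 values of named genes under other settings, 4194 kept direction and side of the threshold, 1489 kept direction but not the threshold, and 32 reversed.

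Without the replicate block (the pairing of both sums of a library), the number of genes past the threshold was 753 with Mef2c and 687 with Gata6, against 1222 and 1278 with it; these are the only ones of the 11 factors beyond 1.5-fold, and the others gave 743 with Hand2, 1241 with Mesp1, 1110 with Foxn4, 142 with Tbx5, 524 with Nkx2-5, 146 with Isl1, 2132 with Myod1, 810 with Myocd and 604 with Gata4. No named gene reversed, 54 of 375 lost the threshold, and the cause was not tested.

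With no scaling factor the share of higher genes moved by 11.7 percentage points for Mef2c (911 higher, 272 lower) and 13.4 for Foxn4 (893 and 405), and with DESeq2 by -13.7 for Gata4 (194 and 133). The median over all genes shifted by at most 0.05 (Foxn4, no scaling), and no named gene reversed under either. DESeq2 gave 62 genes with Tbx5 and 327 with Gata4, limma-voom 57 with Tbx5 and 56 with Isl1, and no filter on counts 215 with Isl1. The cause was not tested.

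Against all cells of the library without the factor, in place of matched ones, the counts were 2354 with Mef2c, 3169 with Gata6, 2570 with Hand2, 3676 with Mesp1, 3626 with Foxn4, 801 with Tbx5, 2396 with Nkx2-5, 1224 with Isl1, 4723 with Myod1, 2846 with Myocd and 2766 with Gata4. Factor by list tests gave 276 past the threshold. This setting compares deeper with shallower cells by construction. The cardiomyocyte list between 1 and 2 or 3 of Gata4, Mef2c and Tbx5 went from 338 to -57.1 CPM, neither past the threshold.

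Each series alone holds fewer libraries and cells by construction. JD gave 506 genes with Mef2c, 380 with Gata6, 237 with Hand2, 301 with Mesp1, 374 with Foxn4, 29 with Tbx5, 84 with Nkx2-5, 13 with Isl1, 1092 with Myod1, 152 with Myocd and 144 with Gata4, and 38 list tests. PZ47-PZ48 gave 446 with Mef2c, 268 with Gata6, 250 with Hand2, 585 with Mesp1, 346 with Foxn4, 24 with Tbx5, 155 with Nkx2-5, 43 with Isl1, 785 with Myod1, 188 with Myocd and 148 with Gata4, and 50 list tests. PZ58 gave 1.7e2 with Mef2c (145 higher and 22 lower), 66 with Gata6, 76 with Hand2, 9 with Mesp1, 26 with Foxn4, 9 with Tbx5, 16 with Nkx2-5, 31 with Isl1, 195 with Myod1, 37 with Myocd and 2 with Gata4. There the permutation test passed 0 list tests (57 unadjusted) and 0 of the tests by number of Gata4, Mef2c and Tbx5 (1 unadjusted), since 6 libraries allow no p under 0.03125.

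Among named genes, JD reversed Mcm5 with Gata6 (log2 fold change 0.04) and Lpl with Myocd (-0.22), and PZ47-PZ48 reversed Cxcl10 with Gata6 (-0.07). PZ58 reversed, for Mef2c, Ecscr with Mef2c (0.11), Emcn with Mef2c (0.97) and Col1a1 with Mef2c (0.01). It also reversed Kdr with Gata6 (-0.31), Cxcl10 with Gata6 (-1.83), Rarres2 with Gata6 (-0.18), Bambi with Hand2 (-0.36), Synpo2 with Mesp1 (-0.09), Map2 with Tbx5 (-0.13), Thy1 with Nkx2-5 (0.17), Klf2 with Myod1 (0.24) and Col2a1 with Gata4 (0.64). None of the reversed values passed the threshold, and the cause was not tested. By number of Gata4, Mef2c and Tbx5, 2 or 3 against 1, the cardiomyocyte list was at -3405 CPM in PZ58, and the skeletal muscle list at 779 CPM in PZ47-PZ48.

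The high read class alone (10 libraries) gave 251 genes with Mef2c, 162 with Gata6, 190 with Hand2, 100 with Mesp1, 92 with Foxn4, 60 with Tbx5, 26 with Nkx2-5, 50 with Isl1, 416 with Myod1, 155 with Myocd and 8 with Gata4. The permutation tests passed 0 list tests (132 unadjusted) and 0 shares across centred clusters (56 unadjusted). The smallest p of both was 0.00196, about the lowest that 10 libraries allow. The high class passed 2 tests by number of Gata4, Mef2c and Tbx5. It reversed Emcn with Mef2c (0.85), Rgs5 with Gata6 (-0.04), Cxcl10 with Gata6 (-0.69), Rarres2 with Gata6 (-0.11), Thy1 with Nkx2-5 (0.01), Gap43 with Myod1 (0.28) and Col2a1 with Gata4 (0.79), and put the cardiomyocyte list at -1448 CPM for 2 or 3 against 1. The low class gave 804 genes with Gata6, 526 with Hand2, 55 with Tbx5, 344 with Nkx2-5, 54 with Isl1 and 503 with Myocd, and put the skeletal muscle list at 198 CPM. Both hold fewer libraries by construction, and the cause of the reversals was not tested.

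Without cells of other types, 161 genes passed with Mef2c, 374 with Myod1 and 249 with Gata4, and 1 test by number of Gata4, Mef2c and Tbx5. Car3 with Mef2c (-0.16), Myh3 with Hand2 (0.65), Actn2 with Hand2 (0.53), Myl7 with Tbx5 (-0.35) and Ube2c with Myod1 (-0.03) reversed, none past the threshold, and the skeletal muscle list for 2 or 3 against 1 was at 92.2 CPM. The setting removes the cells richest in these genes by construction.

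With at least 2 counts of the factor, which leaves fewer cells, the counts were 432 with Foxn4, 73 with Tbx5, 347 with Nkx2-5, 53 with Isl1, 159 with Myocd and 92 with Gata4. Cxcl10 with Gata6 (-0.13) and Stat2 with Myocd (0.07) reversed, as did the smooth muscle list for 2 or 3 against 1 (4551 CPM, 7 libraries, exact permutation test, adjusted p = 0.075). The median share of cells with a factor, 11.4% over the 43 factors, was 4.46% with at least 2 counts, 2.52% in cells thinned to 1500 counts and 0.946% in cells thinned to 500. These settings can only lower the share, so the fall is fixed by their construction. Without the 5% of cells with the most counts, 225 genes passed with Isl1, and Rsad2 with Gata6 (-0.0023), Cxcl10 with Gata6 (-0.46) and Emcn with Isl1 (0.05) reversed; the cause was not tested.

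Of 158 gene list tests of the 8 planned factors, 64 passed with camera, 8 with camera and an estimated correlation, and 48 with fry, and of 58 of the 3 added factors 22, 11 and 20; the cause was not tested. Co-detection passed for 22 of 28 pairs, and for between 15 and 27 under the alternatives. Clusters numbered 15, and 11 to 17 under the alternatives. The smooth muscle-like cluster held 250 cells, 780 at resolution 1.0 and 1186 after centring within read class, and none had that name at resolution 0.3; the cause was not tested.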

Other observations

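The tests of depth between the read classes, of higher totals in cells with Mef2c, of doublets and with 10 strata of depth, the splits of the cells and the setting without other cell types were chosen after the results had been seen. The design has 1 group, so no biological explanation was tested for any of these patterns.

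Some ribosomal and other genes split the libraries into a high and a low read class. Reads shared between near-identical gene copies may have been counted in one class and dropped in the other, as the labels do not state how such reads were treated. Of the 61 genes at least 4-fold apart, 70.5% had a near-identical copy among the annotated transcripts of other genes. The share was 9.84% among genes matched on level, a ratio of 7.17. Of the 61 genes 34 encode ribosomal proteins, against 1 of the matched genes. The ratio therefore does not separate having copies from being a ribosomal protein gene. Depth is argued against, since the median counts per cell of all 26 libraries of the low class lay inside the range of the high class (3563 to 15695). A difference between sequencing runs stays open, because all of PZ58 and none of PZ47-PZ48 is in the high class. Within JD the class also followed the library names, as only libraries named with a pair of numbers were in the high class.

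Muscle genes were higher in cells with Mef2c. Skeletal muscle-like cells, most of which held Mef2c, may account for most of this, as the log2 ratio of the skeletal muscle list was 0.13 without the cells of other types and 2.07 with them. That setting selects cells by their expression, so it cannot tell cells that became muscle-like because of a delivered factor from muscle cells already in the culture. Most of the skeletal muscle-like cells also held Myod1, and each factor was fitted alone, so Mef2c and Myod1 are not separated. Chosen after the clusters were seen, Pax7 and Myf5 of muscle progenitors had 0 CPM in the skeletal muscle-like cells, while Myog stood at 1155 CPM against 3.78 CPM elsewhere. These values do not tell where the skeletal muscle-like cells came from, and their origin was not tested. Higher totals are argued against as the whole cause, since without the 5% of cells with the most counts the mean totals were 15395 and 15023, against 21167 and 18146 with them, and the log2 ratio was 2.56 (higher in 35 of 36 libraries, adjusted p = 0.000241).

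Factor pairs, Mesp1 with Foxn4 and with Nkx2-5 first, were detected together more often than independence gives. The deepest cells do not carry the excess. The median ratio over 28 pairs was 1.34 without the 5% of cells with the most counts and 1.36 with them. A doublet of cells with ordinary totals need not fall among these 5%, so doublets stay open as a source. Residual depth cannot be told apart for most pairs, since pairs with genes outside the pool reached a 95th percentile of 1.52 and 9 of the 28 pairs lay above it. With 10 strata of depth, 11 pairs lay above a percentile of 1.37. Cells that took up more virus could also hold more factors, which these counts do not separate from depth.

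For all 11 modelled factors, the number of genes past the threshold was compared between the real split and 39 others in which the sums with and without the factor were swapped at random within libraries, with limma-voom. For each factor only 1 of the 40 splits, the real one, gave as many genes. The swaps exchange whole sums and never redraw cells. They show that differences kept their direction over libraries, and not where these come from. With 40 splits no share under 1 of 40 was possible, and none was adjusted over the 11 factors. The real and the highest other numbers were 1061 and 3 for Mef2c, 1156 and 3 for Gata6, 725 and 0 for Hand2, 1305 and 2 for Mesp1, 1086 and 1 for Foxn4, 57 and 3 for Tbx5, 444 and 1 for Nkx2-5, 56 and 2 for Isl1, 2080 and 1 for Myod1, 725 and 0 for Myocd, and 356 and 8 for Gata4.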
